A study of Rattus norvegicus with 5 samples.

How the data were processed

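Sequencing libraries from 5 rat ovaries were analysed, 1 from each of 5 treatment groups. Per the labels' protocols, the RNA was extracted with a column kit from Zymo Research, and stranded mRNA libraries were made with a Collibri kit. The submitters' processing notes name fastp, FastQC, MultiQC and HISAT2 and no versions. The program that produced the abundance estimates, the transcript set and the genome build are not given in the sources used here.

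Each library had 1 table of transcripts. Per the file headers, its deposited columns were the transcript identifier, the transcript length, the effective length, the estimated count and the TPM value, a relative abundance scaled by length. An estimated count is the number of reads that the authors' program assigned to a transcript. Reads that fit several near-identical transcripts can be divided among them, so an estimated count need not be a whole number. Only transcripts with an estimate above 0 were listed. An unlisted transcript was taken as 0 counts in that library.

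The identifiers are running numbers, up to 495970, and the files do not pair them with gene names. In the reference gene table used here, of assembly GRCr8, 0 identifiers were found. The unit of every comparison was therefore the transcript, not the gene. The 40 gene lists fixed before the data were examined, their 10000 random lists and the genes to be named could not be evaluated. No percentile, pathway or cell type is reported.

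Within a table, the TPM value divided by the ratio of estimated count to effective length is 1 constant for nearly all transcripts. This was checked in each library. The deposited TPM value was more than 100 times too large against that constant for 110 transcripts in the control library. The number was 71 in the 3-injection cisplatin library, 61 in the 3-injection PRP library, 97 in the 5-injection cisplatin library and 69 in the 5-injection PRP library. The deposited estimated count was more than 100 times too large for 0, 4, 5, 3 and 2 transcripts, in the same order. These counts were divided by 1000. Apart from the TPM values found too large, 0, 3, 4, 1 and 1 transcripts were then still off the constant by more than 1%. The TPM values were then recomputed from the estimated counts and effective lengths, so that each library had the same total. The plan had been to use the TPM column as deposited, and that column was kept as an alternative.

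Fold changes were differences of log2(TPM + 1), which understate the change of low transcripts. A transcript was compared if it reached 5 TPM in at least 1 of the 2 libraries. It was counted as higher or lower at a 2-fold difference or more on that scale. A transcript was said to have whole estimates if its estimated counts lay within 1e-06 of a whole number in both libraries. Such a transcript holds few divided reads, although a whole number also arises when 1 of several copies takes all the reads. An unlisted transcript, taken as 0 counts, also counts as whole. Transcripts were placed in 5 length classes, of 300 to 499, 500 to 999, 1000 to 1999, 2000 to 3999 and 4000 or more bases. The median of length minus effective length over transcripts longer than 5000 bases served as a measure of fragment length.

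The groups came from the sample labels, and 7 comparisons between groups were made. Leaving out a replicate and tests between replicates were not possible with 1 library per group. Overlaps of 2 comparisons are given beside the number for independent lists of the same sizes. For the 2 cisplatin comparisons, which share the control library, 100 simulated sets of 3 unchanged libraries gave values to set beside the overlap. In 1 form of the simulation all spread between the 3 real libraries was taken as noise, and in the other only counting error. Neither form gives a chance level. The first takes any real cisplatin difference as noise, and the other leaves out the spread between animals. Correlations are Spearman rank correlations across transcripts, which are not independent replicates, and carry no p-value.

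Depth limits each value through counting error. TPM values of named transcripts carry exact Poisson 95% intervals on the rounded estimated count, and shares of counts carry Wilson 95% intervals. A fold against 0 counts was computed against a floor of 3 counts in that library and is a lower bound. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

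The counting step was tested on simulated data, with Poisson counts at the real levels and 200 transcripts changed by known amounts. For the 3-injection cisplatin comparison with control, 99 of 100 transcripts changed by 1.5 log2 units were recovered and 18 of 17355 unchanged transcripts were counted. The values were 100 of 100 and 28 of 17311 for 5 injections, 98 of 100 and 17 of 17428 for PRP after 3 injections, and 99 of 100 and 20 of 19399 for PRP after 5 injections. At 2 log2 units, 100 of 100 were recovered in each of these 4 simulations. The changed transcripts were drawn from those at 10 TPM or more, without the most abundant. Only transcripts listed in both libraries were simulated, and no reads were divided among near-identical transcripts. The recovery therefore does not cover lower transcripts. Neither value covers divided reads or transcripts listed in 1 of the 2 libraries.

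The rule for named items, fixed before the data were examined, ranked candidates with at least 10 TPM in 1 of the libraries. For 2 comparisons it took those with the largest smaller fold in each direction. Without names it was applied to transcripts, and only the first in each direction is printed for the cisplatin pair and for the PRP pair.

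The alternatives run were pseudocounts of 0.1 and 5, no filter on level, filters of 1 and 20 TPM, median-of-ratios scaling and quantile normalization. The TPM column as deposited, counts scaled to 1 total per library without a length correction (CPM) and fold changes centred within length classes were added after the data were seen, as were the length classes and the split into whole and other estimates. For CPM the filter was 5 CPM, which passes long transcripts at lower TPM than short ones. FPKM values, rescaling over named genes and the choice of 1 entry per gene name were not run. The deposited tables have no FPKM column, no gene names and 1 entry per identifier. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.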

Results

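Transcript levels were measured by RNA sequencing in ovaries of female Sprague Dawley rats aged 10 to 12 weeks. The study had 5 groups of 6 rats, and 1 ovary per group was sequenced. Premature ovarian insufficiency, an early loss of ovarian function, was modelled with cisplatin, a platinum drug that damages DNA. It was given into the peritoneum at 3 mg/kg each week, either 3 times (the milder model) or 5 times (the more severe model). For each schedule, a second group received platelet-rich plasma (PRP), a platelet concentrate made here from the blood of donor rats. PRP was injected into the ovary by laparotomy 1 week after the last cisplatin dose. The ovaries were collected 2 weeks after PRP, and those of the control group 2 weeks after the last of 5 saline injections. A separate collection time for rats given cisplatin alone is not given in the sources used here.

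The total estimated count was 27088350 in the control library, 30742959 after 3 cisplatin injections and 30453901 after 3 injections with PRP. It was 26383246 after 5 injections and 31822055 after 5 injections with PRP. In the same order, 220507, 191684, 258238, 239393 and 180115 transcripts were listed. Of the 299341 transcripts listed in any library, 109755 were listed in all 5 and 24597 reached 5 TPM in at least 1. The files do not pair transcript numbers with gene names, so the comparisons describe groups of transcripts. With 1 library per group there was no estimate of the spread between animals, no difference was tested and no p-value is given. All values below compare single ovaries. Laparotomy and the antibiotics given after it went with PRP, so their effects cannot be separated from it.

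Fragment length, measured as length minus effective length, was 229.9 bases in the control library, 217 in the 3-injection PRP library and 223 in the 5-injection library. It was shorter in the 3-injection library, at 186 bases, and in the 5-injection PRP library, at 194 bases. Both PRP comparisons set a library with short fragments against one with longer fragments, so no PRP comparison within 1 fragment length could be made. The 5-injection library and the 3-injection PRP library can be compared with the control at similar fragment lengths.

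The first comparisons asked how ovaries differed from control after each cisplatin schedule. After 3 injections, 2218 of 19870 transcripts compared were at least 2-fold higher and 2530 were at least 2-fold lower than in the control ovary. After 5 injections, 2041 of 20635 were higher and 1864 were lower. On the log2(TPM + 1) scale, the largest difference upward in both comparisons, ranked by the smaller of the 2, was in transcript_248181, of 654 bases. It had 0 counts in the control library, 1297 TPM after 3 injections (95% interval 1277 to 1318) and 754 TPM after 5 injections (737 to 772). These levels were at least 5006-fold and at least 2909.8-fold higher than the control floor. The first downward in that ranking was transcript_34099, of 312 bases, at 10015 TPM in the control library (9902 to 10129). It was at 6.48 TPM after 3 injections (4.22 to 9.80) and 3.97 TPM after 5 injections (1.85 to 7.10), or 1546-fold and 2525-fold lower. Other transcripts had larger folds in TPM itself. The estimates of both were not whole in any library that listed them, so their levels are uncertain wherever reads were divided among near-identical transcripts.

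Transcripts under 500 bases made up a large part of these differences. After 3 injections 1044 of 5115 in this class were higher and 1383 were lower, against 195 and 90 of 3791 in the class of 4000 bases or more. After 5 injections the short class had 780 higher and 1020 lower of 5098, and the long class 176 and 61 of 3960. Among transcripts with whole estimates, 156 of 3287 were higher and 138 lower after 3 injections. After 5 injections 287 of 3563 were higher and 68 lower.

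The balance of higher and lower transcripts depended on the scaling. The median log2 fold over all transcripts was 0.21 after 3 injections and 0.22 after 5, and median-of-ratios scaling moved these to -0.09 and 0.01. The counts became 1592 higher and 3547 lower after 3 injections, and 1486 higher and 2379 lower after 5. Quantile normalization gave 1565 higher and 2201 lower after 5 injections, CPM 1381 and 1626, and centring within length classes 1698 and 2014.

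**Figure D1:**
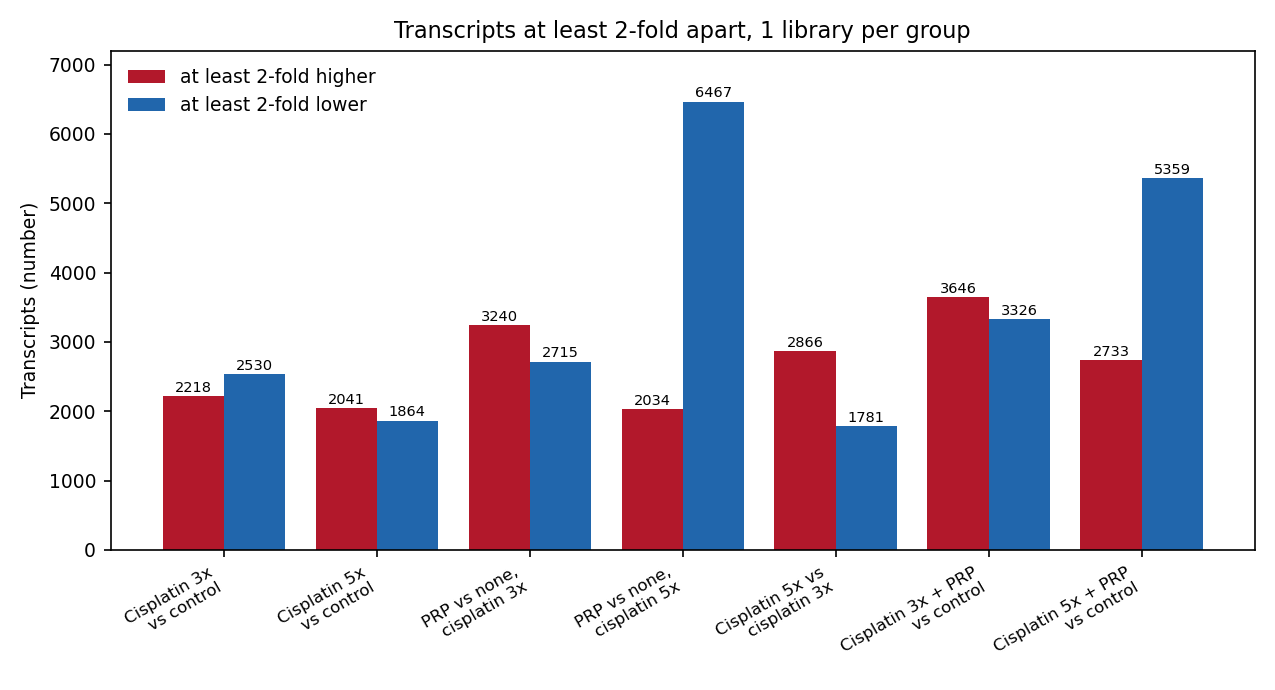
Number of transcripts at least 2-fold higher (red) or lower (blue) in the first-named library of each of the 7 comparisons, with 1 library per group and no error bars. The 5-injection PRP library has 6467 transcripts lower than the 5-injection library and 2034 higher, a balance that quantile normalization moves to 3697 and 3323.

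The 2 schedules shared many differences from control. Of 18546 transcripts compared in both, 699 were at least 2-fold higher after both schedules and 1122 were lower after both, while 152 went opposite ways. Independent lists of these sizes would share 100.2 and 254 transcripts. Both comparisons used the same control library. Simulated unchanged libraries shared 646 higher and 1072 lower transcripts when all spread was taken as noise, and 1.73 and 1.17 with counting error only. The Spearman correlation across transcripts was 0.564 against 0.518 in the simulation with all spread as noise, and the covariance was 0.940 against 0.732. The spread taken as noise includes any real cisplatin difference, so these simulated values are not chance levels. Part of the overlap may come from the shared control, and a single control library cannot be divided to measure that part.

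The schedules were also set against each other. In the 5-injection library 2866 of 20890 transcripts were higher than in the 3-injection library and 1781 were lower, with a median log2 fold of 0.00. Among transcripts with whole estimates 484 of 3706 were higher and 86 lower. The excess of higher transcripts was not even across levels. At a mean below 10 TPM, 1878 were higher and 821 lower, between 10 and 100 TPM 862 were higher and 782 lower, and at 100 TPM or more 126 were higher and 178 lower. With a filter of 20 TPM the balance turned, to 803 higher and 852 lower. The libraries also differed in fragment length, as given above.

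The PRP comparisons asked how an ovary given PRP after cisplatin differed from one given cisplatin alone. After 3 injections, 3240 of 21359 transcripts were at least 2-fold higher with PRP and 2715 were lower. After 5 injections, 2034 of 20458 were higher with PRP and 6467 were lower. In the same ranking on the log2(TPM + 1) scale, the first upward with PRP after both schedules was transcript_308513, of 546 bases. It had 0 counts after 3 injections and 225.7 TPM with PRP (215 to 237), at least 690.4-fold higher. It was at 3.64 TPM after 5 injections (2.33 to 5.23) and 1099 TPM with PRP (1081 to 1118), 302-fold higher, and at 6.36 TPM in the control library (4.78 to 8.26). Other transcripts had larger folds in TPM itself. The first downward was transcript_59392, of 1729 bases. Its level was 844 TPM in the control library (835 to 853), 1045 TPM after 3 injections (1035 to 1056) and 945 TPM after 5 injections (934 to 955). In both PRP libraries its estimated count rounded to 0, at least 12193-fold lower after 3 injections and at least 16655-fold lower after 5. Neither transcript had whole estimates in all libraries that listed it, so both levels are uncertain in the same way.

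The PRP difference varied with transcript length. In the class of 4000 bases or more, 606 of 4582 transcripts were higher and 154 lower with PRP after 3 injections, with a median log2 fold of 0.29. After 5 injections 34 of 3908 were higher and 1388 were lower, with a median of -0.75. In this class, the sign was positive after 3 injections and negative after 5 under median-of-ratios scaling (0.29 and -0.52), quantile normalization (0.24 and -0.21) and CPM (0.32 and -0.67). Among its transcripts with whole estimates the medians were 0.22 and -0.79. In the class under 500 bases the medians were -0.18 after 3 injections and -0.40 after 5, and both turned with some settings. The former was 0.36 without a filter and 0.77 with a filter of 1 TPM, and the latter 0.15 with quantile normalization, 1.01 with CPM and 0.26 with a filter of 20 TPM. The CPM values mix the scaling with a filter set in CPM, which depends on length. Among the transcripts of this class with whole estimates the medians were 0.71, of the opposite sign, over 398 transcripts after 3 injections and -1.12 over 415 after 5. The class of 4000 bases or more held 36.2% of counts in the control library, 35.8% after 3 injections and 41.9% with PRP added. It held 37.7% after 5 injections and 29.0% with PRP added. Wilson 95% intervals of these shares reached at most 0.0185 percentage points to either side.

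The excess of lower transcripts with PRP after 5 injections varied in size with the scaling. The median log2 fold of all transcripts was -0.48, against -0.25 with CPM, -0.23 with median-of-ratios scaling and 0.00 with quantile normalization. The counts were 2615 higher and 6097 lower with CPM, 2739 and 5159 with median-of-ratios scaling, and 3323 and 3697 with quantile normalization. Centring fold changes within length classes gave 3259 higher and 4155 lower. After 3 injections the median was 0.08, and quantile normalization turned the balance to 2638 higher and 2835 lower. Among whole estimates, 644 of 3795 transcripts were higher and 221 lower with PRP after 3 injections, and 87 of 3638 were higher and 1036 lower after 5.

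**Figure D2:**
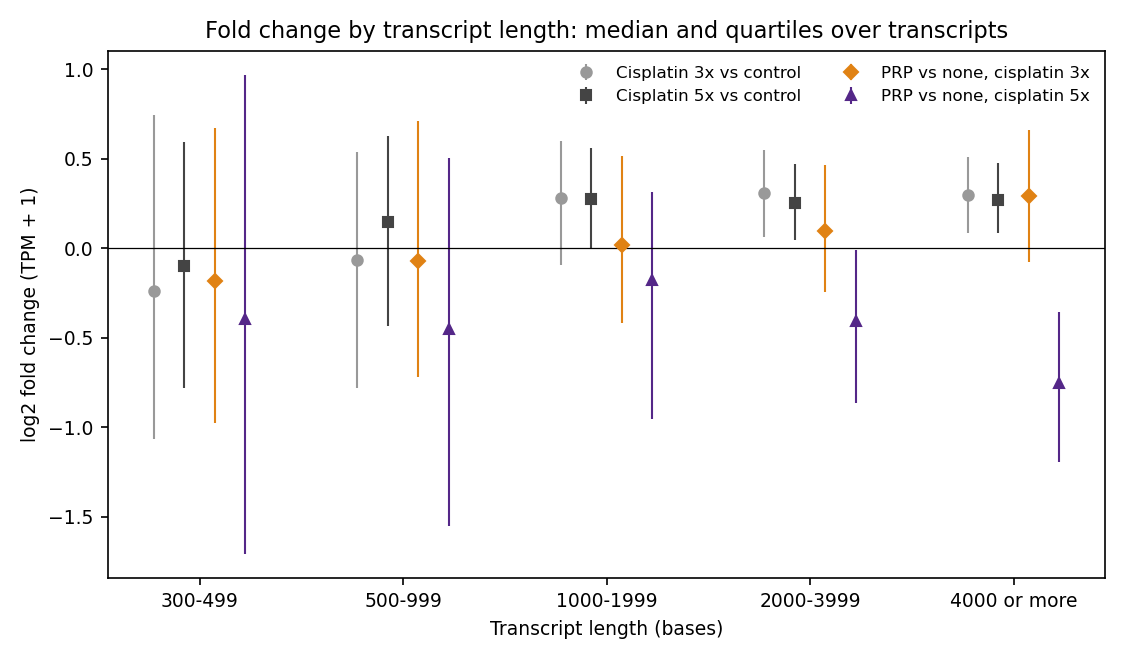
Median log2 fold change of TPM + 1 (points) and quartiles over transcripts (bars) in 5 classes of transcript length in bases, for both cisplatin comparisons and both PRP comparisons. At 4000 bases or more the median is 0.29 for PRP after 3 injections and -0.75 after 5, with the same signs under the 3 other scalings run, while that of cisplatin 3 times against control, 0.30, turns to -0.06 in CPM.

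The PRP differences were not alike after the 2 schedules. Of 17940 transcripts compared in both, 212 were higher with PRP in both and 752 were lower in both, against 160 and 639 for independent lists. Opposite directions were taken by 1600, against 760 for independent lists. Of these, 1122 were higher with PRP after 3 injections and lower after 5, and 478 were the reverse. The correlation across transcripts was -0.161, and -0.228 among the 2870 transcripts with whole estimates. These comparisons share no library. Other pairs of differences that share no library reached a size of 0.294 over all transcripts, so -0.161 lies within their spread. These pairs reuse the same 5 libraries, so their spread is not a chance level.

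**Figure D3:**
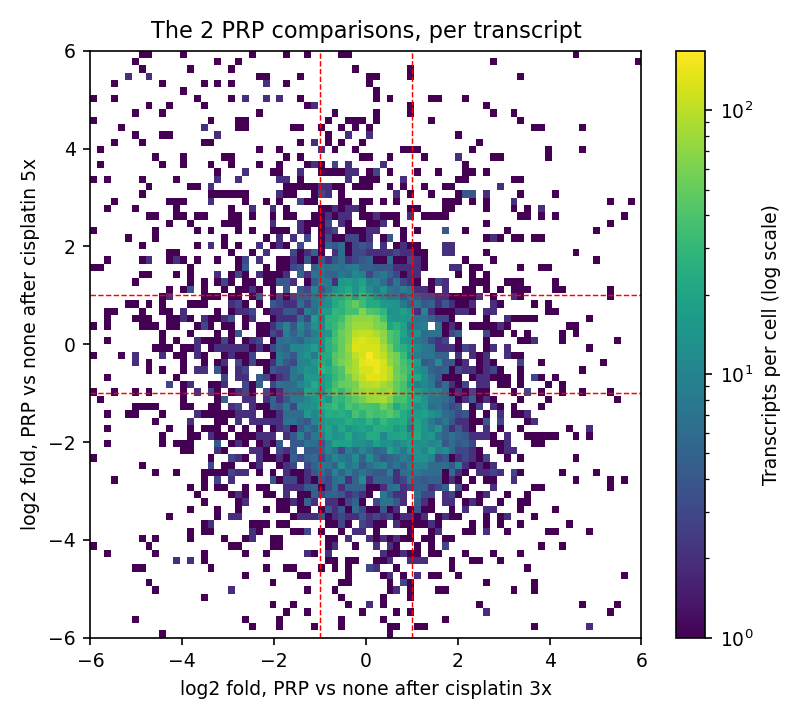
Log2 fold change of TPM + 1 with PRP after 3 cisplatin injections (horizontal axis) and after 5 (vertical axis), with colour giving the number of transcripts per cell on a log scale and dashed lines at 2-fold. The plot shows 17735 transcripts, with 205 outside the axes, and 1122 lie in the lower right corner beyond the lines or outside the axes on that side.

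The last comparisons asked how far ovaries given PRP lay from control. In the 3-injection PRP library 3646 of 21565 transcripts were at least 2-fold higher than in the control library and 3326 were lower. Median-of-ratios scaling gave 2359 higher and 4194 lower, and moved the median from 0.32 to 0.02. The balance also turned with quantile normalization, to 2816 higher and 3741 lower, with CPM, to 2580 and 2911, and with centring within length classes, to 2831 and 3318. In the 5-injection PRP library 2733 of 19202 were higher and 5359 lower, with a median of -0.28. Quantile normalization gave 3699 higher and 4090 lower with a median of 0.07, and centring within length classes 3652 and 3992. Over the 24597 transcripts, the correlation with the control library was 0.747 after 3 injections and 0.657 with PRP added. It was 0.797 after 5 injections and 0.611 with PRP added. The 5-injection PRP library correlated more with the 3-injection library, which also had short fragments (0.731), than with the 5-injection library (0.671). The 3-injection library itself correlated more with the 5-injection library (0.776) than with that PRP library. The 3-injection PRP library correlated at 0.737 with the 3-injection library and 0.728 with the 5-injection library.

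A return toward control would appear as PRP differences opposite to the cisplatin differences. Within 1 schedule both differences use the same cisplatin library, which alone makes the correlation negative. It was -0.361 for 3 injections and -0.20 for 5. How negative the shared library alone would make it was not simulated for these pairs, so their size is not read as a return. Across schedules, with no library in common, the correlation was 0.294 between the 3-injection cisplatin difference and the PRP difference after 5 injections, over 17555 transcripts. It was 0.136 between the 5-injection cisplatin difference and the PRP difference after 3 injections, over 18045 transcripts. The first of these sets short-fragment libraries against longer ones on both sides.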

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

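Of the tests in this part, those of length centring and of whole estimates were written before their own values were seen, but after the medians by length class and the correlations between comparisons had been. Those of abundant transcripts, short fragments, depth, short transcripts and the fragment-length split were chosen after the results were seen. How the length-centring, short-transcript and short-fragment tests were read was revised after their values were seen, the short-fragment test was reworded because its first form depended on the scaling, and the depth test was replaced because the outcome of its first form was fixed by the totals.

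The PRP difference of long transcripts went opposite ways after the 2 schedules. For transcripts of 4000 bases or more, the median log2 fold with PRP after 3 injections exceeded that after 5 injections by 1.04. Also singled out were the 1600 transcripts at least 2-fold apart in opposite directions in the PRP comparisons. Neither difference between schedules was tested, since each rests on 4 single libraries. Among whole estimates, the medians with PRP took opposite signs in each of the 5 length classes. They were 0.71 after 3 injections and -1.12 after 5 under 500 bases, and 0.22 and -0.79 at 4000 bases or more. Among whole estimates the opposite signs were thus not particular to long transcripts. Over all transcripts, the medians under 500 bases were both negative, at -0.18 and -0.40.

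In the 5-injection PRP library more transcripts were lower than higher against cisplatin alone, and it listed the fewest transcripts. The 100 transcripts with the most counts in each library were left out of the scaling. The median was then -0.50, which goes against those transcripts as the cause. They were picked by count, whereas TPM also divides by effective length, so short transcripts at high TPM are not excluded as a cause. Against depth, the library had 1.21 times the total estimated count of the 5-injection library, which listed more transcripts. A length dependence stays open, because centring within length classes gave 1.27 lower per higher transcript but centring on the overall median alone already gave 1.12. A loss of long transcripts alone also cannot be told apart. Transcripts under 500 bases had a median of -0.40, and -1.12 among whole estimates, which go against it. Their median was 0.26 at 20 TPM or more, which goes with it. Their share of counts also goes with it, at 4.47% in the 5-injection library and 8.18% in the 5-injection PRP library. The class from 500 bases rose from 13.9% to 19.0%, and that from 1000 bases from 18.0% to 20.3%. The class from 2000 bases fell from 25.9% to 23.6%. Shares have a fixed total, so a rise in 1 class can follow from a fall in another. An effect of PRP, laparotomy, antibiotics or a different time since the last cisplatin dose may equally be present after 5 injections and was not tested.

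Long transcripts were lower in the same library, and relative to the median of all transcripts, the long-class median was -0.27 in this PRP comparison (-0.42 in CPM, -0.59 with a filter of 20 TPM, 0.03 with 1 TPM). In the PRP comparison after 3 injections, where the library with PRP had the longer fragments, it was 0.21, or 0.26 in CPM, 0.29 with a filter of 20 TPM, 0.0054 without a filter and -0.18 with 1 TPM, so the size and direction of the contrast between schedules in this relative value depend on the filter. Short fragments stay open as the cause, since in the 3-injection library, with the shortest fragments, the relative value against control was 0.0891 but turned to -0.03 in CPM, and it is only 1 library. The filter was then also set in CPM, so this turn mixes the scaling with a filter that depends on length. Against division of reads among near-identical transcripts, the median was -0.79 among whole estimates. An unlisted transcript counts as whole, so this does not exclude reads that all went to another copy. RNA quality, which was not measured here, and a biological difference also remain candidate explanations.

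For the opposite PRP differences, the correlation was -0.228 among whole estimates. This goes against division of reads among near-identical transcripts only in part. Reads that all went to another copy also leave whole estimates, so they are not excluded. The contrast of both PRP differences is the same contrast as short against longer fragments, so the 2 cannot be told apart. At similar fragment lengths, the 3-injection PRP library had 752 higher and 54 lower of 4437 transcripts of 4000 bases or more against control. Their median was 0.55, or 0.23 relative to all transcripts, against 0.27 and 0.05 in the 5-injection library. This is 1 library with PRP, and its difference includes that of cisplatin. Among the 10 ways to part the 5 libraries into 2 and 3, the fragment-length split had a mean correlation of 0.174. The highest other, which set the control and 5-injection libraries apart, had 0.178. Among whole estimates these 2 means were 0.171 and 0.0361. There the split that set the 3-injection PRP and 5-injection libraries apart had 0.159. The 10 splits are too few to judge chance. A schedule-dependent effect of PRP, a preparation difference that goes with fragment length and differences between single rats may each contribute.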

How the results depend on the processing

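CPM, the TPM column as deposited and centring within length classes were added after the data were seen, and the other 7 settings were planned. Of 200 values, for 20 results under 10 settings, 118 stayed within 1.5 times the count, or within the 95% interval of a correlation, and 82 moved. That interval takes transcripts as independent, which they are not, so for correlations it serves only as a rule of size. Neither correlation changed sign. The balance of higher against lower transcripts turned in 6 of 10 settings for 5 injections against control and for the 3-injection PRP library against control: a pseudocount of 5, 20 TPM, median of ratios, quantile normalization, CPM and length centring. It turned in 3 settings for PRP after 3 injections (a pseudocount of 5, 20 TPM and quantile normalization), in 1 for 5 against 3 injections (20 TPM) and in 0 for the other 3 comparisons. With the TPM column as deposited and with a pseudocount of 0.1, none of the 20 results moved. No paired analysis was possible because each group has 1 library. FPKM in place of TPM, rescaling over named genes and the highest entry per gene name were not run. Depth limits low transcripts most, and the filter on level moved more results than any other choice, by its own construction of adding or removing low transcripts. The cause of the other moves was not tested.

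Without a filter and with a filter of 1 TPM the counts were identical, since a transcript under 1 TPM in both libraries cannot differ 2-fold with a pseudocount of 1. Higher and lower transcripts numbered 3859 and 5418 for 3 injections against control, 6407 and 3806 for 5 injections against control, and 10407 and 3185 for 5 against 3 injections. They numbered 17013 and 4668 for PRP after 3 injections and 3460 and 20459 for PRP after 5. Against control they numbered 12798 and 5608 for the 3-injection PRP library and 4384 and 11245 for the 5-injection PRP library. Shared by the PRP comparisons were 476 higher and 1357 lower, and by the cisplatin comparisons 1466 and 2177. The correlation between the 3-injection cisplatin difference and PRP after 5 injections was 0.124 without a filter and 0.311 at 1 TPM. The correlation between the 5-injection cisplatin difference and PRP after 3 injections was 0.107 and 0.227.

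At 20 TPM the counts higher and lower were 1098 and 1112 for 3 injections against control, 707 and 883 for 5 injections against control, and 803 and 852 for 5 against 3 injections. They were 881 and 1110 for PRP after 3 injections, 1173 and 1796 for PRP after 5, 1299 and 1456 for the 3-injection PRP library against control, and 1586 and 1891 for the 5-injection PRP library against control. The PRP comparisons shared 82 and 234, the cisplatin comparisons 301 and 592, and the correlation of the 5-injection cisplatin difference with PRP after 3 injections was 0.0456.

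With a pseudocount of 5, 1647 transcripts were lower for 3 injections against control and 1056 higher and 1302 lower for 5 injections against control. PRP after 3 injections had 1611 higher and 1754 lower, and PRP after 5 had 3584 lower. In the 5-injection library 1379 were higher than after 3 injections, 1877 were higher and 2348 lower in the 3-injection PRP library than in control, and 3471 were lower in the 5-injection PRP library than in control. Lower in both PRP comparisons were 355, higher in both cisplatin comparisons were 436, and the correlation of the 5-injection cisplatin difference with PRP after 3 injections was 0.115.

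Median-of-ratios scaling left 2359 transcripts higher in the 3-injection PRP library than in control. Quantile normalization gave 3323 higher and 3697 lower for PRP after 5 injections, and a correlation of 0.272 between the 3-injection cisplatin difference and PRP after 5. In CPM, 1448 transcripts were higher for 3 injections against control, 480 were lower in both PRP comparisons, 396 were higher in both cisplatin comparisons, and the correlation of the 5-injection cisplatin difference with PRP after 3 was 0.211. Centring within length classes gave 3259 higher and 4155 lower for PRP after 5 injections, 328 higher in both PRP comparisons and a correlation of 0.118 between the 5-injection cisplatin difference and PRP after 3. The opposite directions of the PRP comparisons, 1600 transcripts, ranged from 502 at 20 TPM to 5912 without a filter, above the number for independent lists in each of the 10 settings, and the correlation between them ranged from -0.323 in CPM to -0.127 with quantile normalization.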

Other observations

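The test of reversal and that of divided reads in this part were chosen after the results were seen, as were the level classes, and the spread in the test of reversal was added after its value was seen.

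Abundant and rare transcripts differed in direction with PRP after 5 injections. At a mean of 100 TPM or more, 391 of 1531 transcripts were at least 2-fold higher and 218 lower. Between 10 and 100 TPM, 866 of 9076 were higher and 2047 lower, and below 10 TPM 777 of 9851 were higher and 4202 lower. After 3 injections the order was the other way, with 129 of 1456 higher and 224 lower at 100 TPM or more, and 2155 of 9674 higher and 1431 lower below 10 TPM. These counts by level were not recomputed under the other scalings. The 100 most abundant transcripts held 15.4% of counts in the 5-injection PRP library and 11.9% in the 5-injection library. They held 10.3% in the 3-injection PRP library, 13.2% in the 3-injection library and 13.0% in the control library. Listed in no other library were 9001 transcripts in the 3-injection PRP library, 3927 in the 5-injection library, 2735 in the control library, 1950 in the 5-injection PRP library and 1638 in the 3-injection library.

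Some transcripts reached 100 TPM in 1 library and were not listed in the other. Their number was 62 for 3 injections against control, 35 for 5 injections against control, 42 for PRP after 3 injections and 73 for PRP after 5. Their median lengths were 398.5, 396, 417.5 and 381 bases.

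A candidate explanation for part of the 2-fold differences is that reads of near-identical transcripts were divided differently in each library. Averaged over the 7 comparisons, 25.4% of transcripts with estimates that were not whole were at least 2-fold apart, after adjustment to the same length classes, and 18.5% of those with whole estimates. The ratio of 1.37 lay between the bounds set for and against this cause, so the share due to it stays open. The average hides a difference between comparisons. Against control, the 2 shares were 18.4% and 8.9% after 3 injections, and 16.1% and 10.0% after 5. They lay closer together for PRP, at 25.1% and 22.8% after 3 injections, and 36.6% and 30.9% after 5.

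A hypothesis that PRP moves transcripts back from their cisplatin levels in general predicted negative correlations across schedules, where no library is shared. The lower of the 2 values was 0.136, and it ranged from 0.0456 with a filter of 20 TPM to 0.211 in CPM and 0.227 with a filter of 1 TPM. Apart from those 2 values, pairs of differences that share no library reached a size of 0.218 at the main settings. The value of 0.136 thus lies within their spread. That spread reuses the same 5 libraries, is not a chance level and was not computed for the alternatives. The higher value, 0.294, goes with fragment length. Both values were positive in each of the 10 settings. Each PRP library also correlated less with control than its cisplatin library did (0.657 against 0.747 for 3 injections, 0.611 against 0.797 for 5). The 2 values across schedules were not negative as predicted. Because 0.136 lies within that spread and 0.294 goes with fragment length, they cannot decide the question. The lower correlations with control go against a general return. They rest on single libraries without a spread between animals, so the hypothesis stays open.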
